A study of Mus musculus with 3 samples.

How the data were processed

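Single cells of ectopic tissue masses from CD1 mice, an outbred strain, were profiled by droplet RNA sequencing 5 days after implantation. There were 3 libraries, 1 for each of 3 groups: implants of Matrigel alone, a gel of basement membrane proteins; implants of Matrigel with recombinant human BMP2 in mice given control IgG; and the same BMP2 implants in mice given a neutralizing antibody against activin A. The number of animals behind each library is not given in the sources used here. Libraries were made with the 10x Genomics 3' v3 chemistry, per the labels' protocols, and the submitters' processing notes name Cell Ranger 3.0.2 and the mouse build mm10. The annotation release and the settings for calling cells are not given in the sources used here. The deposited values were UMI counts per gene and cell barcode, whole numbers with no normalization, per the file headers and the values themselves. A UMI is a molecular tag, so each count stands for 1 captured molecule and not for amplified copies. The deposited lists of barcodes and genes carried no measurement.

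The Matrigel library held 9249 barcodes with 44252421 UMIs, the IgG library 6065 barcodes with 46317250 UMIs and the antibody library 6113 barcodes with 38163880 UMIs. Cells were kept with at least 300 genes, at least 500 UMIs and at most 15% of UMIs from mitochondrial genes, which removed 26, 107 and 146 barcodes in that order. Scrublet, run on each library through scanpy 1.11.5, marked 2, 3 and 4 cells as doublets with its automatic threshold, under 0.5% of the cells. As fixed beforehand for that case, the cells with the highest scores were removed instead, at 0.8% per 1000 cells, which took out 682, 289 and 292 cells. The 8541, 5669 and 5675 cells left had medians of 3360, 4162 and 3556 UMIs.

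All 3 libraries were clustered together without batch integration: counts scaled to 10000 per cell and log-transformed, 3000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden resolution 1, with seed 1. Mitochondrial, ribosomal protein, cell cycle and sex-linked marker genes were left out of the variable genes. This gave 27 clusters. Each cluster took the class with the largest share of its fixed markers detected in at least 25% of the cells, and was left unnamed with fewer than 3 detected markers, or where its cells' median UMIs were under 1/3 of their library's and none of its class's markers was among its 10 leading genes. After the clusters had been seen, 2 points were settled that the fixed markers left open: a cluster whose 10 leading genes by fold held more markers of a single other class took that class, and a tie stayed unnamed. Unnamed clusters 0, 2 and 17 held 735, 290 and 155 cells, 1049, 194 and 223 cells, and 104, 103 and 62 cells of the Matrigel, IgG and antibody libraries. Low depth without a leading marker left clusters 0 and 17 unnamed, and a tie left cluster 2 unnamed. Of these, clusters 0 and 2 were nearest to macrophages and cluster 17 to mesenchymal cells. No cluster of a compared class had more markers of another class than of its own among its 10 leading genes.

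Raw UMIs were summed over the cells of a class in each library and expressed as CPM, that is scaled to the same fixed total of UMIs in each class and library. With 1 library per group there was no replicate and no test, so no p-value is given and cells were not treated as replicates. Ratios have exact conditional binomial 95% intervals, levels exact Poisson 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. All of these cover counting error only, not the variation between animals, implants or library preparations. The interval of a ratio of median depths, given under the other observations, came instead from resampling cells and describes only the cells of these libraries. A gene with 0 UMIs was given as a bound against a floor of 3 counts per class and library. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs. Gene lists were fixed before the data were examined. A member was measured with at least 10 UMIs in 1 of the libraries compared and counted as higher or lower at a ratio of at least 1.5. Each list has the median log2 ratio of its measured members, with 1 UMI added to each sum, a 95% interval from Poisson resampling, and its percentile among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries and is no p-value.

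Genes were named by a rule of size fixed before the data were examined. In mesenchymal cells these were the 10 highest and 10 lowest ratios among genes at 100 CPM or more in the higher library, and in macrophages the 5 highest and 5 lowest. Genes whose level was under 10% of that in another class of the same library were left out of this ranking. Free RNA in the droplets could set them. Another class meant a named class with at least 100 cells in that library, and for mesenchymal cells never the chondrocyte-like class. Against the chondrocyte-like class, Col2a1 (254 and 6358 CPM in IgG mesenchymal and chondrocyte-like cells) and Comp (105 and 1155 CPM) would have been left out. Limits of lists to members at 10% or more of every other class used the same classes. Mitochondrial, ribosomal protein, haemoglobin, sex-linked marker and unnamed model genes were also left out of the ranking. A further 16 genes of the activin, BMP and skeletal programmes were always given, together with the most abundant members of each list. Neutrophils had under 100 cells in each library and no endothelial cluster was found, so the lists for those cells were not evaluated. Gene positions come from the GENCODE M21 annotation of the GRCm38 (mm10) build, whose release may differ from the one behind the counts.

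The steps for ratios and lists were tested on simulated counts with 200 genes altered by known folds. The simulated sums were Poisson draws, the model that the intervals assume, so coverage near 95% was built in. This checks the computation only. It cannot show how the intervals hold where a few cells carry most UMIs of a gene. For the IgG and Matrigel mesenchymal cells, 13557 genes were simulated, and the interval held the true ratio for 95.7% of 13357 unaltered genes, 90.0% of 100 genes altered 2-fold and 95.0% of 100 genes altered 4-fold. For the antibody and IgG mesenchymal cells, 12821 genes were simulated, with 95.5%, 97.0% and 97.0%. Random unaltered lists had median percentiles of 45.3 and 49.9 in these comparisons and ranged from 0.1 to 99.8 and from 0.0 to 99.0, so single unaltered lists also came close to either end. Alternatives fixed beforehand were a stricter filter on cells, every deposited barcode without a filter and with doublets, doublets kept, Leiden resolution 2, a class for each cell from its mean marker level, cells thinned to 1000 UMIs, scaling by the median of ratios over genes with at least 50 UMIs and no filter on low list members. Alternatives added after seeing the data counted the chondrocyte-like cluster with the mesenchymal class, left out lymphoid cells, added unnamed clusters 0 and 2 to the macrophages, and used cluster 19 alone. Applying the fixed alternatives to every other list and named gene was also added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.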

Results

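Ectopic masses that form around an implant of BMP2, a growth factor that induces cartilage and bone outside the skeleton, were compared with masses around a carrier implant and with masses of mice treated against activin A, a secreted ligand of the TGF-beta family. The 3 libraries gave 8541 cells for Matrigel alone, 5669 for BMP2 with control IgG and 5675 for BMP2 with the activin A antibody, called here the Matrigel, IgG and antibody libraries. Total depth was 44252421, 46317250 and 38163880 UMIs. Each group had 1 library without replicates, so the values compare these libraries. Intervals are 95% intervals that cover counting error only, except that of a ratio of median depths, which came from resampling cells.

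Macrophages and monocytes were the most abundant class in each library, at 50.7% of cells in the Matrigel library, 49.9% in the IgG library and 49.7% in the antibody library. Mesenchymal cells, marked by collagens and other matrix genes, made up 22.4% (21.5 to 23.3), 20.3% (19.2 to 21.3) and 9.60% (8.85 to 10.4). T and NK cells were at 1.90%, 5.50% and 17.3%, and B cells at 0.012%, 0.071% and 9.34%. Dendritic cells took 2.82%, 5.42% and 3.35%, neutrophils 0.035%, 1.52% and 1.27%, and basophils 0.012%, 1.62% and 1.32%. A chondrocyte-like cluster held 0, 303 and 22 cells; 0 of 8541 Matrigel cells allows a share of up to 0.0432%. This cluster was defined by genes that differ between the libraries, so its size is given to locate the cells and not as a comparison. Unnamed clusters held 22.1%, 10.4% and 7.75% of cells, mostly nearest to macrophages.

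The mesenchymal share was 2.15 points lower in the IgG library than in the Matrigel library (difference -2.15, interval -3.51 to -0.77), but it was 3.20 points higher when the chondrocyte-like cluster was counted with it and 2.22 points higher when each cell was classed on its own. The antibody library had a mesenchymal share 10.6 points below the IgG library (difference -10.6, interval -11.9 to -9.35). With lymphoid cells left out of the denominator the difference was -8.36 points, and with the chondrocyte-like cluster included it was -15.6 points. With every barcode kept, doublets included, it was 0.133 points. In that setting a cluster of 1302 IgG and 385 antibody cells, led by Ibsp, Col2a1 and Acan, was named chondrocyte-like and so left the class. Macrophage shares differed by -0.80 points (interval -2.48 to 0.879) between the IgG and Matrigel libraries and by -0.229 points (interval -2.07 to 1.61) between the antibody and IgG libraries. The first difference was -13.2 points with unnamed clusters 0 and 2 counted as macrophages and -11.5 points with each cell classed on its own, so it depended on how cells were classed. Leaving lymphoid cells out moved the second difference to 14.9 points.

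**Figure D1:**
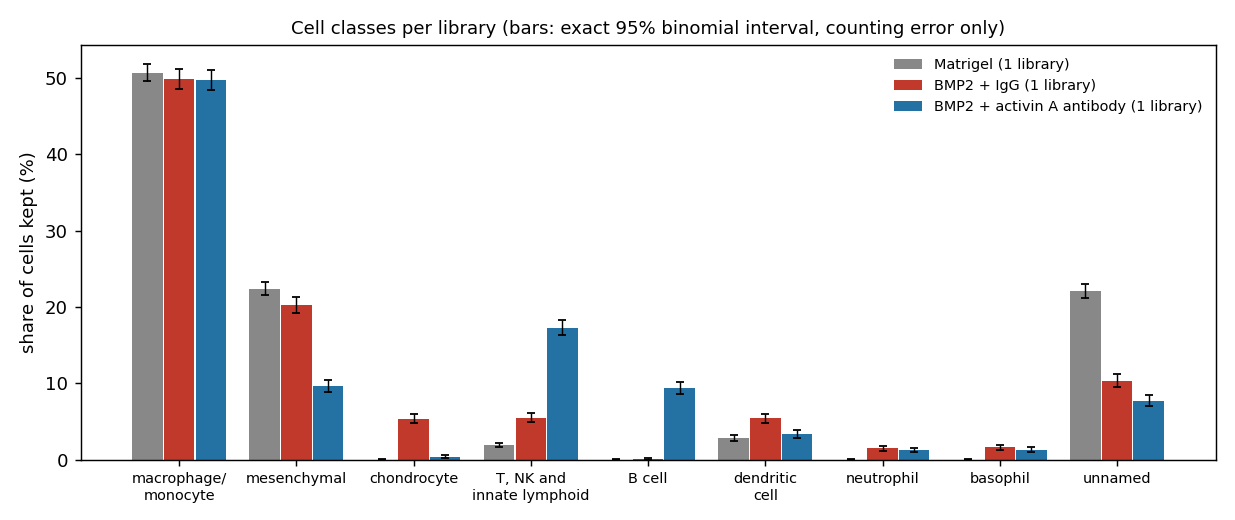
Share of cells kept, in percent, for each cell class in the Matrigel, IgG and antibody libraries, with exact 95% binomial intervals as error bars. Mesenchymal cells were at 22.4%, 20.3% and 9.60%, and B cells at 0.012%, 0.071% and 9.34%.

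Transcripts of Inhba, which encodes the subunit of activin A, were concentrated in the mesenchymal cells of the BMP2 implants. Inhba (ENSMUSG00000041324; chromosome 13, 16011851 to 16031621, plus strand, protein-coding) stood at 25.6 CPM in mesenchymal cells of the Matrigel library (23.4 to 28.0, 489 UMIs), 717 CPM in the IgG library (706 to 728, 15913 UMIs) and 795 CPM in the antibody library (780 to 811, 10014 UMIs). At 1000 UMIs per cell, 1.53%, 28.0% and 29.7% of mesenchymal cells had an Inhba UMI, against 11.9%, 70.7% and 58.2% before thinning at median depths of 9066, 17843 and 19870 UMIs. Thinning left out 15, 4 and 2 cells. Chondrocyte-like cells held 503 CPM in the IgG library and 353 CPM in the antibody library. In macrophages Inhba was at 0.623, 7.20 and 2.76 CPM, and 0.071%, 0.726% and 0.44% of thinned macrophages had a UMI. Col2a1, a cartilage collagen that macrophages lack, stood at 0, 16.3 and 1.28 CPM in the same cells, and in 0%, 2.00% and 0.183% of them after thinning. In the IgG macrophages Inhba lay below Col2a1 and was read as background. Inhba lay above Col2a1 in macrophages of the Matrigel and antibody libraries, and its source there was not tested. Free RNA could give this order in the antibody library, where mesenchymal cells held 795 CPM of Inhba and 206 CPM of Col2a1. In the Matrigel library Col2a1 is no measure of background, since its mesenchymal cells held 1 Col2a1 UMI. Median depths of the macrophages were 2942, 3376 and 4405 UMIs. Dendritic cells had 0, 6.10 and 13.9 CPM, and T and NK cells 0, 6.44 and 3.01 CPM, all from 24 UMIs or fewer.

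**Figure D2:**
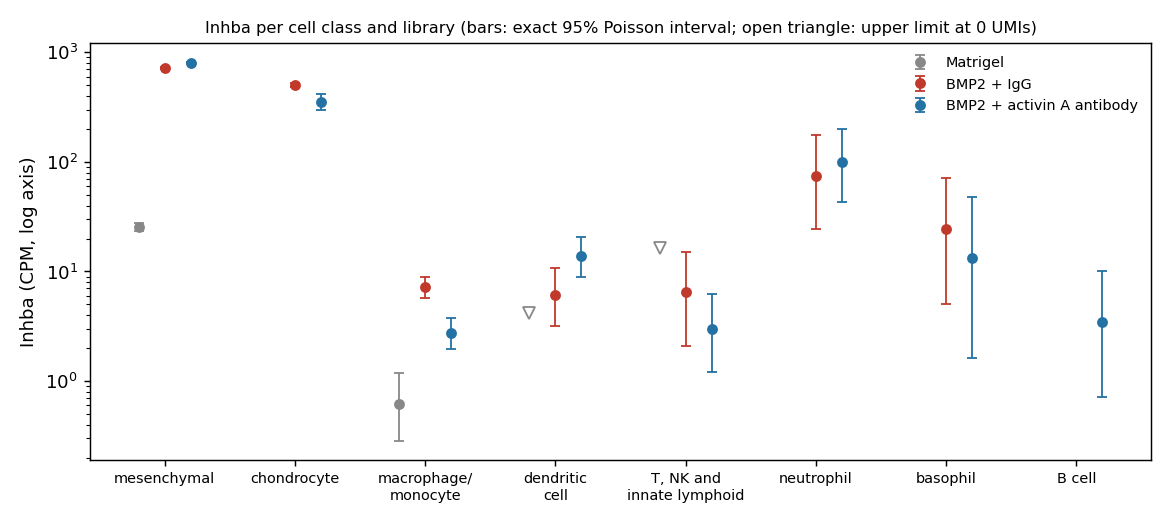
Inhba level in CPM on a log axis for each cell class and library, with exact 95% Poisson intervals as error bars and open triangles for upper limits at 0 UMIs. Mesenchymal cells of the IgG and antibody libraries stood at 717 and 795 CPM, above the 25.6 CPM of the Matrigel library.

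The comparison of the IgG with the Matrigel library asked what BMP2 in the implant, with control IgG given to the mice, was accompanied by. The labels name no IgG for the Matrigel library, so BMP2 and IgG cannot be told apart here. In mesenchymal cells of the IgG library, genes of cartilage and bone matrix were far higher than in the Matrigel library, Inhba was 28.0-fold higher (25.6 to 30.7), and genes of resting fibroblast progenitors were lower. Ibsp, which encodes bone sialoprotein, had 0 UMIs in the Matrigel cells and 327 CPM in the IgG cells, at least 2083-fold higher. Acan, the cartilage proteoglycan aggrecan (chromosome 7, 79053483 to 79115099), had 1 UMI in the Matrigel cells and 653 CPM in the IgG cells, a ratio of 12490 (2242 to 493400). Col2a1 (chromosome 15, 97975602 to 98004695) also had 1 Matrigel UMI and 254 CPM in the IgG cells, a ratio of 4858 (872 to 191900). Both genes were higher still when chondrocyte-like cells were included, at 1196 CPM for Acan and 1444 CPM for Col2a1. Different clusters held most of the class in these libraries: clusters 3, 4 and 12, with 697, 879 and 318 cells, in the Matrigel library, and cluster 19, with 945 of 1148 cells, in the IgG library. Inhba, Tnn, Fmod and Acta2 were among the leading genes of cluster 19, and Igfbp5, Pi16, Clec3b, Itih5, Pla1a, Akr1c18 and Efhd1 among those of cluster 4.

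The remaining highest ratios in the IgG mesenchymal cells were those of Comp, a cartilage matrix protein (0.628 and 105 CPM in the Matrigel and IgG cells, 167-fold, 95.6 to 324), Fmod, the collagen-binding fibromodulin (49.0 and 1396 CPM, 28.5-fold), Edil3 (27.2-fold), Col11a1, a cartilage collagen chain (19.9-fold), Tnn, tenascin N (17.2-fold), and Wwp2 (14.5-fold). The lowest ratios were those of Dlk1, a marker of preadipocytes (125 and 2.07 CPM, 60.2-fold lower, 45.0 to 82.5), Islr2 (16.7-fold lower), Igfbp5, an insulin-like growth factor binding protein (1189 and 72.9 CPM, 16.3-fold lower), and Dpp4, a surface peptidase of fibroblast progenitors (14.6-fold lower). Efhd1, Akr1c18, Pla1a, Ace, Itih5 and Clec3b followed, at 14.5-, 12.8-, 12.3-, 11.5-, 10.5- and 10.5-fold lower.

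Of 20 measured chondrogenic genes, 19 were higher and 1 lower in the IgG mesenchymal cells, with a median log2 ratio of 4.63 (4.35 to 5.20) and a percentile of 100. Besides Acan and Col11a1, Wwp2 stood at 25.1 and 364 CPM and Sox9, the master regulator of chondrocytes (chromosome 11, 112782224 to 112787760), at 53.6 and 324 CPM. Osteogenic genes were higher for 9 of 11 and lower for 0, with a median of 1.69. Spp1 stood at 83.9 and 373 CPM, Pth1r at 46.2 and 150 CPM, and Runx2, which directs osteoblast formation, at 31.8 and 86.9 CPM. BMP-SMAD1/5 target genes were higher for 9 of 14 and lower for 0, with a median of 0.98 (0.85 to 1.14) and a percentile of 100. The Id genes are direct targets of SMAD1/5 downstream of BMP receptors: Id3 stood at 243 and 665 CPM, Id1 at 45.9 and 110 CPM, and Id2 at 131 and 151 CPM. TGF-beta/activin-SMAD2/3 target genes were higher for 5 and lower for 2 of 16, with a median of 0.17 (0.12 to 0.21) and a percentile of 76.5. That median was 0.0065 (-0.028 to 0.040) with the chondrocyte-like cluster and 0.022 (-0.016 to 0.057) with a class per cell. Among these, Tgfbi was at 114 and 645 CPM, Pmepa1 at 578 and 641 CPM, and Cyr61 at 391 and 225 CPM.

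**Figure D3:**
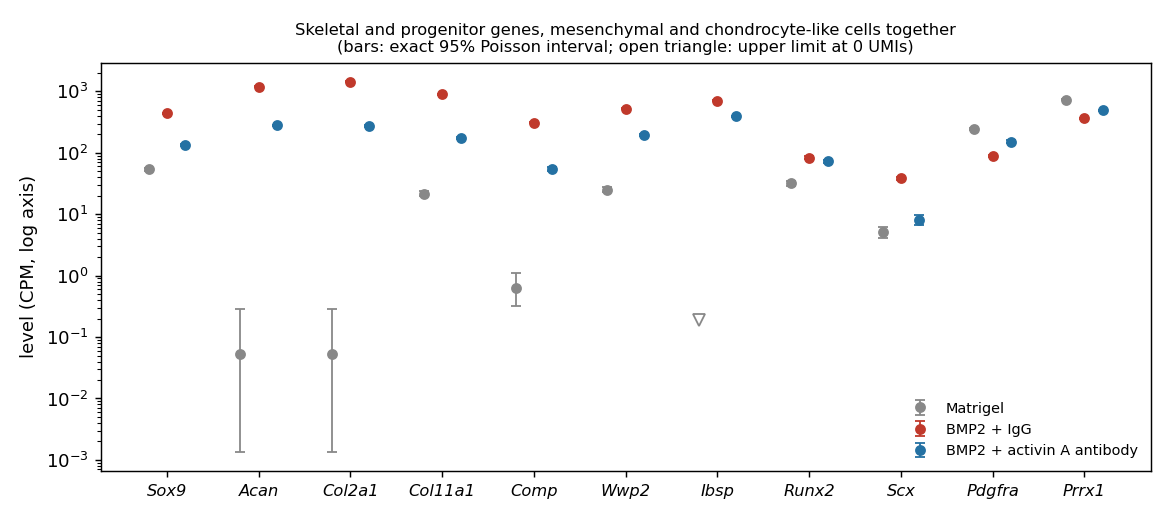
Levels of skeletal and progenitor genes in CPM on a log axis, in mesenchymal and chondrocyte-like cells together, for the 3 libraries, with exact 95% Poisson intervals as error bars and open triangles for upper limits at 0 UMIs. Col2a1 stood at 0.052 CPM in the Matrigel library, 1444 CPM in the IgG library and 272 CPM in the antibody library. Chondrocyte-like cells numbered 0, 303 and 22 in these libraries.

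All 19 mesenchymal progenitor genes were lower in the IgG mesenchymal cells, with a median log2 ratio of -2.51 and a percentile of 0. Ly6a stood at 2178 and 816 CPM, Dpt at 1940 and 341 CPM, Cd34 at 908 and 128 CPM, and Pi16 at 872 and 98.8 CPM. Pdgfra, a receptor of fibroblast progenitors, was at 243 and 99.3 CPM, and Prrx1 at 736 and 402 CPM. Contractile myofibroblast genes were higher for 7 and lower for 1 of 10, with a median of 1.29 and Acta2, smooth muscle actin, at 195 and 1004 CPM. Proliferation genes were higher for 17 and lower for 0 of 22, with a median of 0.91, and hypoxia and glycolysis genes were higher for 11 and lower for 1 of 18, with a median of 0.80. Top2a stood at 97.6 and 173 CPM, and the glycolytic enzyme Ldha at 1182 and 2040 CPM. Interferon-stimulated genes were lower for 14 and higher for 0 of 15, with a median of -1.24, and Ifi27l2a was at 533 and 108 CPM. Adipogenic genes were lower for 10 and higher for 0 of 11, with a median of -0.99, and Fabp4 was at 955 and 359 CPM, with 76.9% and 97.6% of its UMIs in 10 cells. Dissociation and immediate early genes, which respond to tissue handling, were lower for 12 and higher for 2 of 17, with a median of -1.32 in the same cells.

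Matrix-degrading enzymes and their inhibitors were higher for 2 and lower for 8 of 16, with a median of -0.80, Timp2 at 1599 and 463 CPM and Timp1 at 691 and 1454 CPM. Interstitial matrix genes were higher for 2 and lower for 7 of 23, with a median of 0.06 and Col3a1 at 25889 and 12000 CPM. Tendon genes were higher for 4 and lower for 5 of 10, with a median of -0.48 whose interval of -0.84 to 0.23 included 0; it was 0.15 without the member that free RNA could set. Scx, a tendon transcription factor, was at 5.07 and 40.1 CPM. Receptors, SMADs and activin antagonists were higher for 2 and lower for 6 of 19, with a median of -0.27. Acvr1, a BMP type I receptor, stood at 37.6 and 83.7 CPM, and Fst, the activin antagonist follistatin, at 138 and 85.1 CPM. Acvr1b, Acvr2a and Acvr2b were at 16.9 and 14.01, 9.63 and 9.19, and 2.46 and 3.20 CPM. TGF-beta superfamily ligands and BMP antagonists were higher for 7 and lower for 11 of 22, with a median of -0.28, mouse Bmp2 at 2.04 and 0.721 CPM and Inhbb at 11.9 and 2.70 CPM. Without Bmp2, which free RNA could set, the median was 0.155 (-0.14 to 0.18). Inflammatory cytokines and chemokines were higher for 7 and lower for 5 of 20 (median -0.31), or 4 and 4 of the 11 at 10% or more of every other class (median -0.36), Wnt pathway genes higher for 6 and lower for 4 of 12 (median 0.46, but 0.056, -0.18 to 0.30, without the member that free RNA could set), and Hedgehog and Notch pathway genes higher for 4 and lower for 6 of 12 (median -0.38). Ccl2 was at 432 and 119 CPM, Wnt5a at 40.2 and 73.5 CPM, and Hes1 at 127 and 48.7 CPM. Unfolded protein response genes were higher for 3 and lower for 0 of 13, with a median of 0.27 and Hspa5 at 799 and 961 CPM.

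Macrophages of the IgG library had higher levels of Chil3, a chitinase-like protein (0.346 and 129 CPM, 372-fold, 159 to 1147), Ctsk, the protease cathepsin K (37.1-fold, with 76.5% of the IgG UMIs in 10 cells), Arg1, arginase 1 (chromosome 10, 24915221 to 24927484; 47.1 and 1317 CPM, 28.0-fold), Tgm2 (22.2-fold) and Spp1 (18.8-fold) than those of the Matrigel library. They had lower levels of Retnla, a marker of alternative activation (5690 and 652 CPM, 8.72-fold lower), Fcna (5.37-fold lower), the complement gene C4b (4.99-fold lower), Cd209f (4.45-fold lower) and Lyve1, a marker of resident macrophages (4.25-fold lower). Chil3, C4b and Cd209f have closely similar gene copies, among which the counting could divide reads. Clusters 7, 13, 6 and 9 held most Matrigel macrophages, with 1522, 882, 619 and 560 cells, and clusters 1, 18 and 8 most IgG macrophages, with 892, 542 and 511 cells. Chil3 was among the leading genes of cluster 18, Arg1 of cluster 8, and Retnla, Fcna, Cd209f and Lyve1 of cluster 13.

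Osteoclast genes were higher for 8 and lower for 0 of 9 in the IgG macrophages, with a median log2 ratio of 2.66, and Acp5, the osteoclast acid phosphatase, stood at 24.8 and 191 CPM. SMAD2/3 target genes were higher for 10 and lower for 0 of 16 in these cells, with a median of 0.76 (0.40 to 1.13). Tgfbi was at 421 and 1163 CPM and Pmepa1 at 27.4 and 192 CPM; over the 7 members at 10% or more of every other class the median was 1.19, with 4 higher and 0 lower. Hypoxia and glycolysis genes were higher for 15 and lower for 0 of 18 (median 1.07, Pkm at 727 and 1595 CPM), and inflammatory cytokines and chemokines higher for 11 and lower for 2 of 18 (median 0.90, and 0.72 over the 15 members at 10% or more of every other class; Ccl8 at 3746 and 6176 CPM). Interferon-stimulated genes were higher for 7 and lower for 1 of 15 (median 0.51). Proliferation genes were lower for 18 and higher for 0 of 22 (median -0.98, Top2a at 124 and 58.4 CPM). Alternative-activation and resident genes were higher for 6 and lower for 9 of 20 (median -0.30), MHC class II genes higher for 1 and lower for 1 of 7 (median 0.09, H2-Eb1 at 2610 and 748 CPM), and dissociation and immediate early genes higher for 2 and lower for 4 of 17 (median -0.15).

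The Inhba ratio of the IgG to the Matrigel mesenchymal cells was 42.9 at Leiden resolution 2 and 1.71 with every barcode kept, doublets included. In the latter, the BMP2 type of mesenchymal cells was named chondrocyte-like and so left the class, and the median of the chondrogenic genes was 2.73.

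The comparison of the antibody with the IgG library asked what treatment against activin A was accompanied by in BMP2 implants. In mesenchymal cells of the antibody library, cartilage genes were lower and genes of fibroblast progenitors higher than in the IgG library, while Inhba was 1.11-fold higher (1.08 to 1.14). Acan stood at 653 CPM in the IgG and 201 CPM in the antibody cells (3.25-fold lower, 3.12 to 3.40), Col11a1 at 427 and 120 CPM (3.58-fold lower), Comp at 105 and 37.4 CPM (2.81-fold lower) and Sox9 at 324 and 122 CPM (2.64-fold lower). In the antibody library 10 cells held 48.1%, 52.7% and 62.6% of the Acan, Col11a1 and Comp UMIs. With chondrocyte-like cells included, Col2a1 was at 1444 and 272 CPM (5.31-fold lower, 5.13 to 5.49) and Acan at 1196 and 279 CPM. Without them Col2a1 was at 254 and 206 CPM, and 10 cells held 93.1% of its UMIs in the antibody mesenchymal cells and 50.9% in the IgG cells. Within cluster 19 Col2a1 was at 290 CPM in the IgG and 274 CPM in the antibody library, a ratio of 0.947 (0.903 to 0.992). The 5.31-fold difference includes the 303 IgG and 22 antibody chondrocyte-like cells. Cluster 19 held 945 of 1148 mesenchymal cells in the IgG library and 331 of 545 in the antibody library, and cluster 4, led by Igfbp5, Pi16 and Clec3b, held 68 and 149.

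The gene with the highest ratio was Cck, which encodes the peptide hormone cholecystokinin (chromosome 9, 121489824 to 121495694), at 0.315 CPM from 7 UMIs in the IgG and 281 CPM from 3538 UMIs in the antibody mesenchymal cells, 891-fold (432 to 2218). Its UMIs lay in 111 antibody cells, with 47.2% of them in 10 cells, and the Matrigel cells held 73 UMIs. Igfbp5 was 5.07-fold higher, Clec3b 4.04-fold and Pi16 3.96-fold, followed by Aqp1 (3.68-fold), Efemp1 (3.64-fold), Tppp3 (3.52-fold), the chemokine receptor Ackr3 (3.41-fold), Pla1a (3.40-fold) and the immediate early gene Dusp1 (3.33-fold). Within cluster 19, Igfbp5 was instead lower in the antibody library, at a ratio of 0.514 (0.376 to 0.691), and Clec3b and Pi16 stood at only 2.02 and 3.39 CPM. The lowest ratios were those of Car3, a carbonic anhydrase (113 CPM in the IgG cells and 0 UMIs in the antibody cells, at least 473-fold lower), Fabp4, the adipocyte fatty acid binding protein (359 and 15.9 CPM, 22.6-fold lower), and G0s2 (7.60-fold lower). In the IgG cells 10 cells held 99.96% of the Car3 UMIs and 97.6% of the Fabp4 UMIs. H19, Ddit4 and Clec11a were 3.02-, 2.65- and 2.56-fold lower.

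Of 19 measured chondrogenic genes, 1 was higher and 16 were lower in the antibody mesenchymal cells, with a median log2 ratio of -1.54 (-1.69 to -1.44) and a percentile of 0. With chondrocyte-like cells included, 2 were higher and 22 lower of 24, with a median of -2.40. Osteogenic genes were higher for 1 and lower for 6 of 11 (median -0.62), with Ibsp at 327 and 163 CPM, 27.6% and 73.4% of its UMIs in 10 cells, Spp1 at 373 and 853 CPM and Runx2 at 86.9 and 71.9 CPM. BMP-SMAD1/5 target genes were higher for 0 and lower for 5 of 14 (median -0.29, -0.42 to -0.15, percentile 2.1, but -0.055, -0.31 to 0.079, within cluster 19), with Id3 at 665 and 643 CPM and Id1 at 110 and 123 CPM. SMAD2/3 target genes were higher for 2 and lower for 1 of 16, with a median of -0.04 whose interval of -0.09 to 0.02 included 0 and a percentile of 58.9. Tgfbi stood at 645 and 594 CPM and Pmepa1 at 641 and 463 CPM. Contractile myofibroblast genes were higher for 0 and lower for 6 of 10 (median -1.03), with Acta2 at 1004 and 409 CPM. Tendon genes were higher for 2 and lower for 4 of 8 (median -0.67), with Scx at 40.1 and 7.31 CPM and Fmod at 1396 and 800 CPM. At Leiden resolution 2 a cluster with Acta2, Tagln, Myl9 and Scx among its leading genes, of 10 Matrigel, 275 IgG and 45 antibody cells, was named pericyte or smooth muscle and left the class; the medians of contractile myofibroblast genes and tendon genes were then -0.85 and -0.86.

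Mesenchymal progenitor genes were higher for 11 and lower for 1 of 19 in the antibody mesenchymal cells, with a median log2 ratio of 0.99, Dpt at 341 and 675 CPM and Pdgfra at 99.3 and 157 CPM. Within cluster 19 this median was 0.31. Dissociation and immediate early genes were higher for 12 and lower for 0 of 17, with a median of 0.92 in the same cells. Matrix-degrading enzymes and their inhibitors were higher for 7 and lower for 2 of 16 (median 0.48), with Timp1 at 1454 and 2459 CPM. Inflammatory cytokines and chemokines were higher for 7 and lower for 7 of 20 (median 0.44), or 6 and 2 of the 11 at 10% or more of every other class (median 0.59), with Ccl2 at 119 and 224 CPM. Interferon-stimulated genes were higher for 6 and lower for 1 of 15 (median 0.56), with Ifi27l2a at 108 and 318 CPM, but within cluster 19 their median was -0.40. Adipogenic genes were higher for 1 and lower for 9 of 11 (median -3.92), and within cluster 19 the 5 measured members had a median of 0.25.

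Proliferation genes were higher for 0 and lower for 3 of 22 (median -0.29), hypoxia and glycolysis genes higher for 0 and lower for 3 of 18 (median -0.21), and interstitial matrix genes higher for 2 and lower for 2 of 23 (median -0.17). Receptors, SMADs and activin antagonists were higher for 3 and lower for 4 of 19 (median -0.03), with Acvr1 at 83.7 and 64.6 CPM, Acvr1b at 14.01 and 8.50 CPM, Acvr2a at 9.19 and 8.02 CPM, Acvr2b at 3.20 and 2.06 CPM and Fst at 85.1 and 93.1 CPM. TGF-beta superfamily ligands and BMP antagonists were higher for 9 and lower for 8 of 22 (median 0.01), with Inhbb at 2.70 and 8.81 CPM, mouse Bmp2 at 0.721 and 2.22 CPM and Tgfb3 at 107 and 48.4 CPM. Wnt pathway genes were higher for 2 and lower for 5 of 12 (median -0.28), Hedgehog and Notch pathway genes higher for 2 and lower for 5 of 11 (median -0.44), and unfolded protein response genes higher for 1 and lower for 0 of 13 (median 0.02). Prrx1 stood at 402 and 502 CPM. Within cluster 19 the median was -0.049 (-0.13 to 0.0054) for proliferation, -0.10 for hypoxia and glycolysis, -0.26 for interstitial matrix and 0.091 for unfolded protein response genes, -0.87 for contractile myofibroblast and -0.47 for tendon genes, and -0.21 (-0.44 to -0.074) for TGF-beta superfamily ligands and BMP antagonists, with 4 higher and 7 lower of 17.

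**Figure D4:**
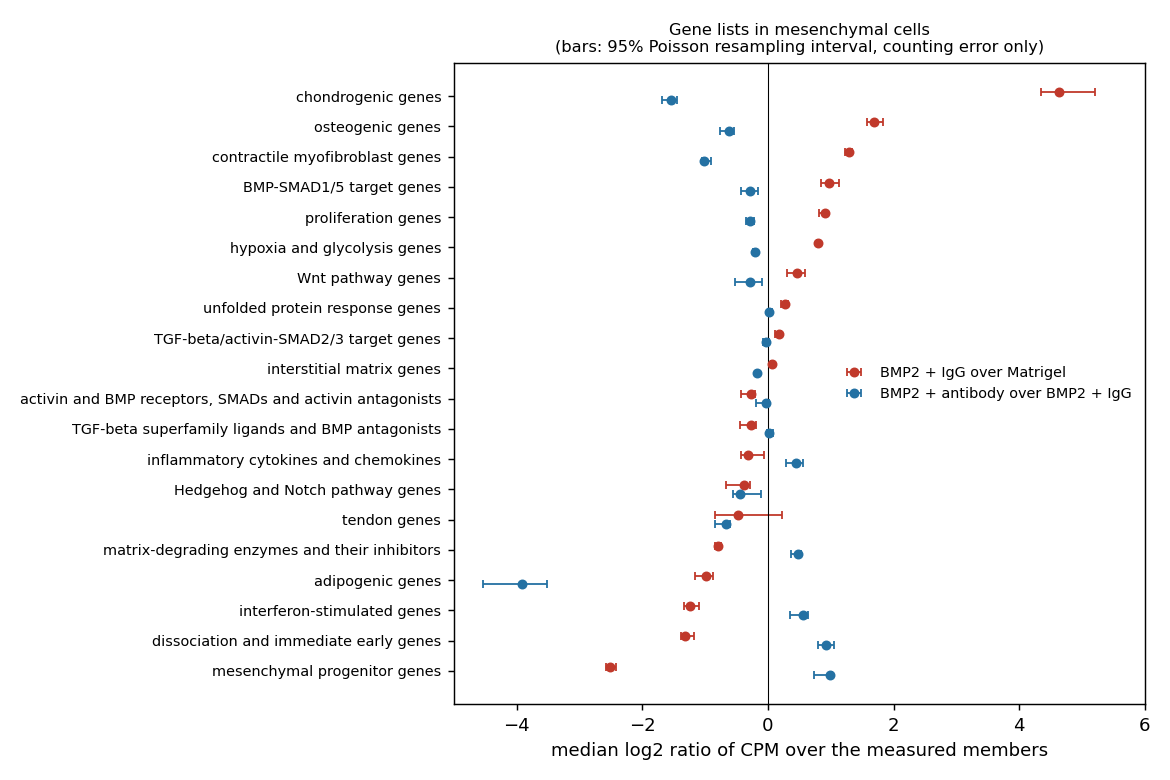
Median log2 ratio of CPM over the measured members of each gene list in mesenchymal cells, for the IgG against the Matrigel library and the antibody against the IgG library, with 95% Poisson resampling intervals as error bars. Chondrogenic genes lay at 4.63 in the first comparison and -1.54 in the second, and progenitor genes at -2.51 and 0.99; both comparisons contain the IgG library.

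Macrophages of the antibody library had higher levels of Cxcl2, a neutrophil-attracting chemokine (39.6 CPM in the IgG and 188 CPM in the antibody macrophages, 4.75-fold, 4.30 to 5.26), Ltc4s, a leukotriene synthase (3.83-fold), Lyve1 (3.18-fold), the ubiquitin gene Ubb (2.98-fold) and the scavenger receptor Cd36 (2.97-fold) than those of the IgG library. They had lower levels of Lilr4b (3.57-fold lower), which has a closely similar copy, the interferon-induced chemokine Cxcl10 (3.42-fold lower), the fractalkine receptor Cx3cr1 (3.14-fold lower), Pmepa1 (chromosome 2, 173224458 to 173276533; 192 and 62.9 CPM, 3.05-fold lower, 2.83 to 3.30) and Ccl24 (2.66-fold lower). Arg1 stood at 1317 and 1923 CPM. Clusters 1, 8 and 18 held 892, 511 and 542 IgG macrophages and 1082, 869 and 427 antibody macrophages, and cluster 11, led by interferon-stimulated genes including Cxcl10, held 291 and 62.

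SMAD2/3 target genes were higher for 1 and lower for 9 of 16 in the antibody macrophages, with a median log2 ratio of -0.70 (-0.99 to -0.42), and Tgfbi was at 1163 and 700 CPM. Over the 7 members at 10% or more of every other class, the median was -0.37 (-0.45 to -0.29), with 1 higher and 2 lower. Interferon-stimulated genes were higher for 0 and lower for 10 of 15 (median -0.80), with Isg15 at 183 and 81.7 CPM. Dissociation and immediate early genes were higher for 11 and lower for 0 of 17 (median 0.68), with Fos at 421 and 700 CPM. Inflammatory cytokines and chemokines were higher for 7 and lower for 4 of 19 (median 0.15), or 7 and 1 of the 16 at 10% or more of every other class (median 0.39), with Ccl2 at 431 and 783 CPM. Osteoclast genes were higher for 1 and lower for 1 of 9 (median -0.30), with Acp5 at 191 and 146 CPM and Mmp9 at 136 and 284 CPM. MHC class II genes were higher for 1 and lower for 1 of 7 (median -0.32), alternative-activation and resident genes higher for 2 and lower for 3 of 20 (median 0.01), proliferation genes higher for 0 and lower for 2 of 22 (median -0.16), and hypoxia and glycolysis genes higher for 1 and lower for 1 of 18 (median -0.17).

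The Inhba ratio of the antibody to the IgG mesenchymal cells was 0.817 at Leiden resolution 2, below 1, and the median of the SMAD2/3 targets in these cells lay between -0.63 and 0.16 over the alternatives. The median gene of the macrophages shifted by -0.14 on the log2 scale between these libraries under total scaling, against -0.09 in the mesenchymal cells.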

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

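The tests on lymphocytes were chosen only after the result was seen, and so was the size, at least 1.5-fold in 1 of the classes, above which opposite signs in mesenchymal cells and macrophages are listed here.

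Medians of several lists had opposite signs in the 2 main cell classes, beyond counting error in each; the difference between the classes was not tested. In the IgG over the Matrigel library, the median log2 ratio of inflammatory cytokines and chemokines was -0.31 in mesenchymal cells, where members went both ways with 7 higher and 5 lower, and 0.90 in macrophages, with 11 higher and 2 lower. Interferon-stimulated genes stood at -1.24 and 0.51 in the same comparison. Proliferation genes stood at 0.91 and -0.98. In the antibody over the IgG library, interferon-stimulated genes were at 0.56 in mesenchymal cells and -0.80 in macrophages, but the mesenchymal value was -0.40 within cluster 19.

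Some signals lay outside the comparisons and appeared mainly in the antibody library. B cells made up 9.34% of its cells, against 0.071% in the IgG library and 0.012% in the Matrigel library. T cells of cluster 23, led by Lef1, Tcf7 and Bcl11b, made up 10.5% of its cells, against 0.353% and 0.082%. Haemoglobin transcripts took 0.814% of the UMIs over all its barcodes, against 0.268% and 0.049%.

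The T cells of cluster 23 may come from lymphoid tissue or blood caught in the harvested mass. At 1000 UMIs per cell, Cd44, which marks activated and memory T cells, was found in 1.95% (0.978 to 3.46) of cluster 23 cells of the antibody library against 11.8% (1.46 to 36.4) of those of the IgG library, where 17 cells were too few to decide. Lymphoid tissue as the source of the B cells was not tested. Blood as the source of these T cells or of the B cells stayed open. Haemoglobin was higher, at 0.814%, but the interval of the difference in neutrophil share to the IgG library, -0.686 to 0.186 points, included 0. An effect of the antibody on lymphocytes was not tested and, with 1 library, is confounded with how that mass was taken.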

How the results depend on the processing

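The alternatives with the chondrocyte-like cluster, without lymphoid cells, with clusters 0 and 2 and with cluster 19 alone, and the use of the fixed alternatives for all other lists and genes, were chosen after seeing the data. So was the rule for a reversal outside the main results: it was first a change of sign beyond the counting interval, and was then limited to values of at least 1.5-fold and genes with at least 10 UMIs in 1 library, which left fewer reversals. No paired analysis was possible because each group has 1 library. A main result could count as reversed only where its reported interval excluded no difference. Changes of sign in the macrophage shares and in the antibody over IgG median of the SMAD2/3 targets were therefore counted as moved or stayed. Of the alternative values of the main results, 42 stayed within the counting interval, 56 moved beyond it and 4 reversed. The reversals were the mesenchymal share in 3 cases, of which the 0.133 below has an interval that included 0, and Inhba of the antibody over the IgG library at resolution 2. Of those of the other lists and named genes, 636 stayed, 500 moved and 15 reversed. Counting intervals are narrow at this depth, so many moves are small; they leave out the variation between animals, which was not measured. No cell filter here means every deposited barcode, doublets included, so 2 choices change at once.

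The mesenchymal share of the IgG minus the Matrigel library was -2.15 points as reported, 2.22 with a class per cell, 3.20 with the chondrocyte-like cluster, -19.3 with no cell filter, -0.345 with doublets kept and -11.8 at Leiden resolution 2. The antibody minus IgG difference was -10.6 as reported, 0.133 with no cell filter, -12.2 with doublets kept, -2.74 at resolution 2, -14.8 with a class per cell, -8.36 without lymphoid cells and -15.6 with the chondrocyte-like cluster. Without a cell filter the BMP2 type of mesenchymal cells (19, 1302 and 385 cells of the Matrigel, IgG and antibody libraries) was named chondrocyte-like, and at resolution 2 part of it was named chondrocyte-like or pericyte, which removed these cells from the class by construction. For macrophages, the IgG minus Matrigel share was -0.799 as reported and 2.25 with the stricter filter, -3.50 with doublets kept, 2.35 at resolution 2, -11.5 with a class per cell, 1.16 without lymphoid cells and -13.2 with clusters 0 and 2. The antibody minus IgG share was -0.229 as reported and -4.01 with the stricter filter, -3.22 without a filter, -3.77 at resolution 2, -3.01 with a class per cell, 14.9 without lymphoid cells and -2.11 with clusters 0 and 2.

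The Inhba ratio of the IgG to the Matrigel library, 28.0 as reported, was 1.71 without a cell filter, 42.9 at resolution 2 and 33.2 with thinned cells. For the antibody to the IgG library, 1.11 as reported, it was 1.03 without a cell filter, 0.817 at resolution 2, 1.15 with a class per cell, 1.18 with median-of-ratios scaling, 1.16 with the chondrocyte-like cluster and 1.26 in cluster 19. Chondrogenic genes kept their direction in every alternative run. Their IgG over Matrigel median of 4.63 was 3.92 with the stricter filter, 2.73 without a filter, 2.31 at resolution 2, 5.94 with a class per cell, 4.23 with no filter on low values and 5.51 with the chondrocyte-like cluster. Their antibody over IgG median of -1.54 was -1.94 with the stricter filter, -2.17 without a filter, -1.91 with doublets kept, -1.76 at resolution 2, -2.05 with a class per cell, -2.40 with the chondrocyte-like cluster and -1.31 in cluster 19. The BMP-SMAD1/5 median of 0.98 was 1.29 at resolution 2, and that of -0.29 was -1.50 without a filter, -0.15 with doublets kept and -0.055 in cluster 19. The SMAD2/3 median of 0.17 was 0.21 with the stricter filter, 0.047 without a filter, 0.39 at resolution 2, 0.022 with a class per cell and 0.0065 with the chondrocyte-like cluster. That of -0.04 was -0.63 without a filter, -0.10 at resolution 2, -0.12 with thinned cells, 0.0496 with median-of-ratios scaling, 0.0307 with the chondrocyte-like cluster and 0.16 in cluster 19.

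The reversals among other results came from 3 settings. Without a cell filter, ratios of the IgG to the Matrigel library became 1.12 for Fst, 0.790 for Runx2 and 1.16 for Pdgfra, and list medians 0.034 for matrix-degrading enzymes and their inhibitors, -0.43 for contractile, -0.13 for hypoxia and glycolysis, 1.62 for adipogenic and 0.52 for interferon-stimulated genes. For the antibody to the IgG library, Pdgfra became 0.966 and contractile genes 0.32. At resolution 2 Fabp4 became 1.72 and adipogenic genes 0.28, and in cluster 19 Fabp4 became 1.80, adipogenic genes 0.25 and Igfbp5 0.514. Intervals of Runx2, of the matrix-degrading enzymes and of Pdgfra in the antibody over IgG comparison included no difference. The losses without a cell filter go with the changed class above, which was not tested apart from the changes of filter and doublets. Those of Fabp4 and the adipogenic genes at resolution 2 and in cluster 19 go with the few IgG cells that hold most Fabp4 UMIs. Igfbp5 stood at 11.6 CPM in the IgG and 5.94 CPM in the antibody cells of cluster 19, against 72.9 and 370 CPM in the class. Most of its class level thus lay in cells outside cluster 19. Why Igfbp5 was lower within cluster 19 was not tested.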

Other observations

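The tests of free chondrocyte RNA, of depth and of macrophage makeup were chosen after the result was seen, the first of them after levels of Col2a1 in macrophages had been seen, and cluster 19 alone is an alternative chosen after seeing the data; the other tests here were written down before their results were seen, for patterns found in these data.

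Other immune clusters were told apart by their leading genes. Cluster 24, led by Tnfrsf4, Ctla4 and Foxp3, genes of regulatory T cells, held 14 Matrigel, 122 IgG and 245 antibody cells. Cluster 15, led by Gzma, Ncr1 and Prf1, genes of natural killer cells, held 39, 140 and 103 cells, and cluster 14, led by Tcrg-C4, Cxcr6 and Gata3, held 102, 30 and 38. Among dendritic cells, cluster 21, led by Xcr1, Flt3 and Clec9a, held 138, 44 and 20 cells, and cluster 10, led by Ccl17 and Cd209a, held 74, 232 and 157. These counts locate cells and were not compared between libraries.

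Expression of Cck in the antibody mesenchymal cells was not a matter of cluster makeup alone, since within cluster 19 it stood at 0.361 CPM in the IgG and 373 CPM in the antibody library. Within the same cluster Tppp3 was 4.81-fold and Aqp1 4.16-fold higher in the antibody library, and Scx had a ratio of 0.213. Car3 and Fabp4 UMIs of the IgG mesenchymal cells lay almost wholly in 10 cells. At Leiden resolution 2 an adipocyte-like cluster led by Car3, Fabp4 and Adipoq held 26 Matrigel, 9 IgG and 0 antibody cells, and an epithelial-like cluster led by Krt8, Prlr and Krt18 held 6, 16 and 12. These genes were singled out after their values were seen.

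Lower chondrogenic genes in the antibody than in the IgG mesenchymal cells were set against technical explanations. Lower depth of the antibody cells is argued against, because their median UMIs were 1.11-fold those of the IgG cells (1.05 to 1.24). A smaller part of cluster 19 as the whole cause is argued against by a median of -1.31 (-1.47 to -1.21) within that cluster, although the clusters were built on genes that may include these. Free RNA of chondrocyte-like cells is argued against as the whole cause, since the summed level of the list in IgG macrophages was 5.65% of that in IgG mesenchymal cells, with a median of 4.68% per member. An effect of activin A neutralization, a difference between the mice or implants and a finer makeup within cluster 19 stay open, since each group has 1 library.

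Lower SMAD2/3 target genes in macrophages of the antibody library, with a median of -0.70, were set against technical explanations. Free RNA from mesenchymal cells cannot be told apart from expression, because the 7 members at 10% or more of every other class had a median of -0.37, between the values that would have decided. For a different makeup of the class, 8 clusters weighted as in the IgG library gave -0.57. This was just short of the bound that a test written beforehand had set. A later test with a looser bound used clusters 8 and 1, which hold most antibody macrophages. Their medians were -0.79 (-1.03 to -0.47) and -0.90 (-1.07 to -0.71), while other clusters reached 0.43. Makeup between clusters cannot lower values within a cluster, but these medians included members that free RNA could set. Makeup together with free RNA therefore stays open. Pmepa1 stood at 300 CPM in the IgG and 56.1 CPM in the antibody cells of cluster 1, 309 and 87.9 CPM in cluster 8, and 36.9 and 37.3 CPM in cluster 18. An effect of activin A neutralization was not tested. It stays open beside free RNA, alone or with cluster makeup, a finer makeup within clusters and differences between the mice or implants.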
